A study of Homo sapiens with 24 samples.

How the data were processed

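The series profiled RNA bound by SRSF1, a serine/arginine-rich splicing factor, by eCLIP, in which protein and RNA are crosslinked, the protein is pulled down with an antibody and the attached RNA is sequenced. Per the labels, 24 samples were made, 16 of them SRSF1 eCLIP and 8 of them inputs. They came from MCF7, an oestrogen receptor-positive breast cancer line, and HEK293T, an embryonic kidney-derived line. Cells were kept in normoxia or in 0.2% oxygen for 24 hours, and were treated with a scrambled antisense oligonucleotide (ASO) or an ASO against the nuclear long noncoding RNA MALAT1. Each combination of line, ASO and oxygen level had 2 eCLIP samples.

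The deposited data used here are 8 annotated peak lists, 2 for each cell line and oxygen level. The cell line and oxygen level of a list were taken from the list's own name. The names give neither the ASO nor the sample, so no list was assigned to an ASO, and scramble and MALAT1 ASO were not compared. Each condition had 4 eCLIP samples and 2 lists, so a list may hold 1 sample or several. Lists 1 and 2 were treated as 2 lists of a condition, and their spread may include the ASO, replicate cultures or technical variation. Nothing in the labels says that the samples came from separate cultures, so permutation p-values measure only the spread between lists.

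Per the submitters' processing notes, base calls were made with bcl2fastq 2.20 and the genome build was GRCh38. The aligner, the peak caller, the annotation release, the use of the inputs and any pooling of samples are not given in the sources used here. Per the file headers, each row of the deposited lists holds a position, a strand, gene names and identifiers, a gene part and an exon type. The lists hold no score, fold enrichment or p-value per peak, and sequencing depth is unknown. Starts were read as counted from 0 and are printed counted from 1. Among peaks naming 1 gene found in the RefSeq table of GRCh38.p14, 99.1% to 99.5% lay inside that gene's span, so gene coordinates from that table are given beside the peaks.

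Of 155360 rows in the 8 lists, 26653 (17.2%) repeated a position and strand of the same list. Each position was counted once. A gene was called bound when at least 1 peak named it. Peaks that named several genes, 14.7% to 19.3% of a list, were counted for each gene, so overlapping and antisense partners share peaks. The lists named 13456 Ensembl gene identifiers, of which 13235 had a current symbol. Exon types in the MCF7 lists hold gene identifiers in place of untranslated region classes, so 5 gene parts comparable between the lines were used: exon with coding sequence, exon without it, exon-intron, intron and intergenic. UTR classes are given for HEK293T alone.

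Hypoxia-only genes were bound in both hypoxia lists and in neither normoxia list of a line, and normoxia-only genes the reverse. The same counts were made for the other ways of pairing the 4 lists. Peak regions were merged where peaks overlapped by at least 1 base on the same strand. List-level values were compared by two-sided exact permutation of the oxygen labels within a line, which cannot go below p = 0.33, and over both lines with labels permuted within each, which cannot go below p = 0.0556. No list-level comparison could therefore reach 0.05. Fixed gene lists, 13 in number with 378 genes, were tested among hypoxia-only and normoxia-only genes by two-sided Fisher's exact test against genes bound in at least 2 of the 4 lists of the line, with Benjamini-Hochberg adjustment over 52 tests. The same lists were tested between the cell lines over 26 tests, against genes in at least 4 of the 8 lists, in any list of the line or in any list of both lines. These tests between the lines and their backgrounds were not among the choices made before the data were examined. Genes are not independent replicates in these tests. Shares of peaks carry exact Clopper-Pearson 95% confidence intervals, which cover counting error only.

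Named genes followed a rule fixed before the data were examined. It takes MALAT1, NEAT1 and SRSF1. It adds the 10 genes per line and direction with the largest smaller-of-2 peak number among hypoxia-only or normoxia-only genes, the 10 genes with most peaks per line, and the 10 per line bound in all 4 of its lists and none of the other line's. It also takes up to 4 members per fixed gene list with the largest difference in mean peak number between oxygen levels, and 5 regions per line and direction. The rule ranked regions and broke ties by the authors' peak value. Since the lists hold none, covered bases and total peak number took its place. Motifs planned for the comparison were not analysed here, because they need a genome sequence.

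The code was checked on simulated data. For each line, lists were drawn from its pooled peaks at the real lengths, and 200 hypoxia-only genes were planted in them. Of the planted genes, 100% were recovered in MCF7 (10915 genes in the step) and 100% in HEK293T (8002 genes). A planted gene meets the definition of a hypoxia-only gene by construction, so full recovery checks the code and says nothing about sensitivity. Without planting, the same step found 545 hypoxia-only genes in MCF7 and 336 in HEK293T. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives included a minimum of 2 peaks per gene, protein-coding genes, 50% reciprocal overlap, ignoring strand, shares of bases, another background and leaving out each list. Further alternatives were chosen after seeing the data: rows as deposited, lists drawn at random to equal length (20 draws), peaks naming 1 gene or none, leaving out chromosome 21, peaks of at least 5 bases, and merging within 50 bases.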

Results

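SRSF1 binding was profiled in MCF7 and HEK293T cells under normoxia and after 24 hours at 0.2% oxygen. The series title asks how hypoxia alters RNA processing of genes near nuclear speckles, and 8 peak lists were available, 2 per cell line and oxygen level. After each position was counted once, the MCF7 normoxia lists 1 and 2 held 21927 and 11017 peaks, and the MCF7 hypoxia lists held 29670 and 18892. The HEK293T normoxia lists held 6811 and 16212 peaks, and the HEK293T hypoxia lists held 11449 and 12729. Peaks were narrow, with median widths of 5 to 7 bases and a longest peak of 140 bases.

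MALAT1 (ENSG00000251562), the nuclear long noncoding RNA that an antisense oligonucleotide (ASO) in this series targets (chromosome 11, 65497738 to 65506516, GRCh38), held peaks in all 8 lists. The HEK293T normoxia lists held 9 and 5 MALAT1 peaks and the hypoxia lists 5 and 3. In MCF7 the normoxia lists held 4 and 3 and the hypoxia lists 4 and 3. The means were 7 ± 2.83 in normoxia and 4 ± 1.41 in hypoxia in HEK293T (SD, n = 2 lists). The difference of -3 was -0.5 with peaks of at least 5 bases, and -1 without HEK293T normoxia list 1 to -5 without normoxia list 2. NEAT1, the architectural RNA of paraspeckles (chromosome 11, 65422798 to 65445540), held 9 and 15 peaks in HEK293T normoxia and 13 and 15 in hypoxia, and 8 to 11 in the MCF7 lists. Peaks in the SRSF1 transcript itself (chromosome 17, 57989038 to 58007246) numbered 5 and 5 in HEK293T normoxia and 6 and 7 in hypoxia, against 4 and 4 and then 5 and 5 in MCF7. No list was tied to an ASO, so MALAT1 peak numbers were not compared between ASOs.

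The first comparison was between oxygen levels in HEK293T. Of the 10 leading genes bound only in the hypoxia lists, 3 belonged to the fixed hypoxia-response list. NDRG1, a stress-induced gene and common hypoxia marker (chromosome 8, 133237175 to 133297252), held 5 and 6 peaks in the hypoxia lists and 0 in both normoxia lists. PFKFB4, which sets fructose-2,6-bisphosphate levels (chromosome 3, 48517684 to 48563136), held 5 and 5. HILPDA, a lipid droplet protein induced by hypoxia (chromosome 7, 128455878 to 128458418), held 5 and 3. The glycolytic enzyme gene GAPDH held 5 and 5, the cyclin gene CCNG2 held 6 and 3, and NAMPT, an enzyme of NAD synthesis, held 3 and 4. WDR45B held 7 and 4. The other leading genes, each at 0 in both normoxia lists, were AHRR (3 and 3), AKIRIN2 (3 and 3) and MBOAT2 (2 and 7).

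Among the fixed gene lists, hypoxia response was enriched among HEK293T hypoxia-only genes. It had 7 of its 25 background members among the 319 hypoxia-only genes, against 1.26 expected from a background of 6336 genes. The odds ratio was 7.48, with adjusted p = 0.00874 by Fisher's exact test and Benjamini-Hochberg adjustment over 52 tests. The members were ANKRD37, EGLN3, HILPDA, INSIG2, KDM3A, NDRG1 and PFKFB4, several of them known targets of hypoxia-inducible factors. No other test passed. Most other lists had little room to pass among these genes, because HEK293T normoxia list 2 alone bound nearly all members bound in that line. It bound 17 of 18 glycolysis, 26 of 26 hnRNP, 42 of 44 nuclear speckle and spliceosome and 41 of 42 translation members, against 17 of 27 for hypoxia response. Their lack of enrichment therefore does not set hypoxia response apart. The hypoxia-response enrichment was lost when only peaks of at least 5 bases were used (odds ratio 3.07). It was also lost when HEK293T hypoxia list 1 or list 2 was left out with a background of genes in any list, with odds ratios of 4.02 and 3.91. Over all settings tried, the adjusted p ran from 0.00158 to 0.938 by Fisher's exact test.

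Counted over peaks, the hypoxia-response list held 14.7 (95% confidence interval 7.04 to 27.0) and 16.7 (10.98 to 24.2) of every 10000 peaks in the HEK293T normoxia lists. In the hypoxia lists it held 68.1 (53.9 to 85.0) and 58.1 (45.7 to 72.9). Of its 27 members bound in any HEK293T list, 14 had more peaks in both hypoxia lists than in either normoxia list, and 0 had fewer in both. Chance gives 16.7% in each direction only for values without ties in lists of equal length. Peak numbers here are small and list lengths differ, so that figure is no exact baseline, and the share over all bound genes was not worked out. P4HA1, a collagen prolyl hydroxylase subunit, held 1 and 1 peaks in normoxia and 9 and 10 in hypoxia. VEGFA, the angiogenic growth factor, which the naming rule did not pick, held 1 and 2 and then 5 and 6. PFKFB3 held 0 and 3 and then 2 and 6. The difference of 47.5 per 10000 exceeded the spread between lists and was 29.2 with peaks of at least 5 bases, but exact permutation within the line could not go below its value of p = 0.33 (n = 2 lists each).

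Glycolysis genes held 42.6 (28.5 to 61.1) and 33.9 (25.6 to 44.1) of every 10000 peaks in HEK293T normoxia and 77.7 (62.5 to 95.6) and 59.7 (47.1 to 74.7) in hypoxia. PGK1, phosphoglycerate kinase, held 5 and 8 peaks in normoxia and 22 and 20 in hypoxia. HK2 held 0 and 2 and then 4 and 1, while LDHB, a lactate dehydrogenase subunit gene, held 9 and 8 and then 6 and 4. Of 18 bound members, 7 had more peaks in both hypoxia lists than in either normoxia list, 1 had fewer and 10 overlapped. The difference of 30.5 per 10000 was larger than the spread between lists, with exact permutation p = 0.33, and became 4.22 with peaks of at least 5 bases. No measure of transcript abundance was used here, so peak numbers do not separate more SRSF1 on a transcript from more transcript.

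**Figure D1:**
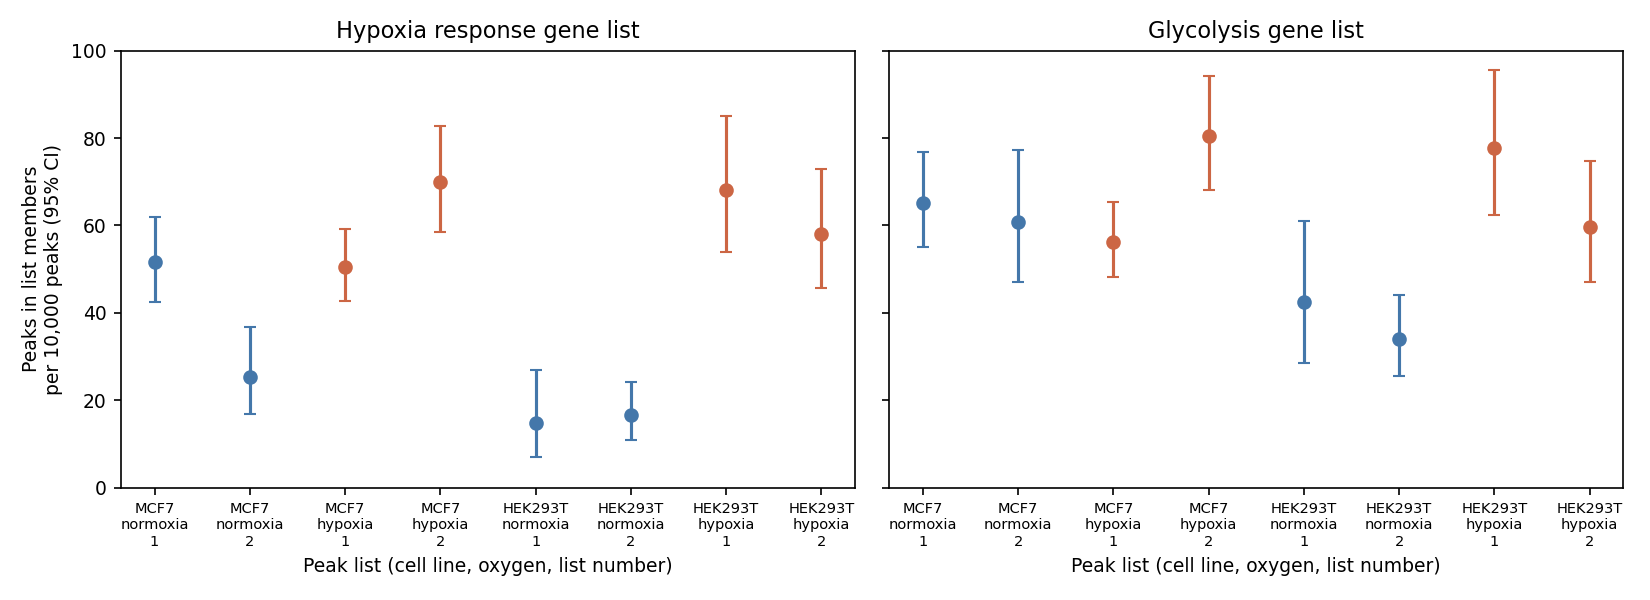
Peaks in members of the hypoxia response and glycolysis gene lists per 10000 peaks (vertical axis) in each of the 8 peak lists (horizontal axis), blue for normoxia and orange for hypoxia, with exact 95% confidence intervals that cover counting error only. For the hypoxia response list, both HEK293T hypoxia lists (68.1 and 58.1) lie above both normoxia lists (14.7 and 16.7), while the list labelled MCF7 normoxia 1 (51.5) lies with the MCF7 hypoxia lists.

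Genes bound only in the HEK293T normoxia lists numbered 287, and 1536 when HEK293T normoxia list 1 was left out. EEF1AKMT2, a lysine methyltransferase gene, held 3 and 6 peaks, and VPS9D1 held 3 and 4, its antisense partner VPS9D1-AS1 sharing part of the same interval with 2 and 3. MTOR, the growth-control kinase gene (chromosome 1, 11106535 to 11262551), held 2 and 3 peaks in normoxia and 0 in both hypoxia lists. CERCAM (2 and 3), CWC27 (3 and 2), MZT1 (3 and 2), SLC35A3 (2 and 3), DSG2-AS1 (2 and 2) and FAM242F (2 and 2) completed the leading genes. No fixed gene list was enriched among them. Most lists had little room to be. HEK293T hypoxia list 1 alone bound 25 of 27 hypoxia-response and 44 of 44 nuclear speckle and spliceosome members bound in that line.

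**Figure D2:**
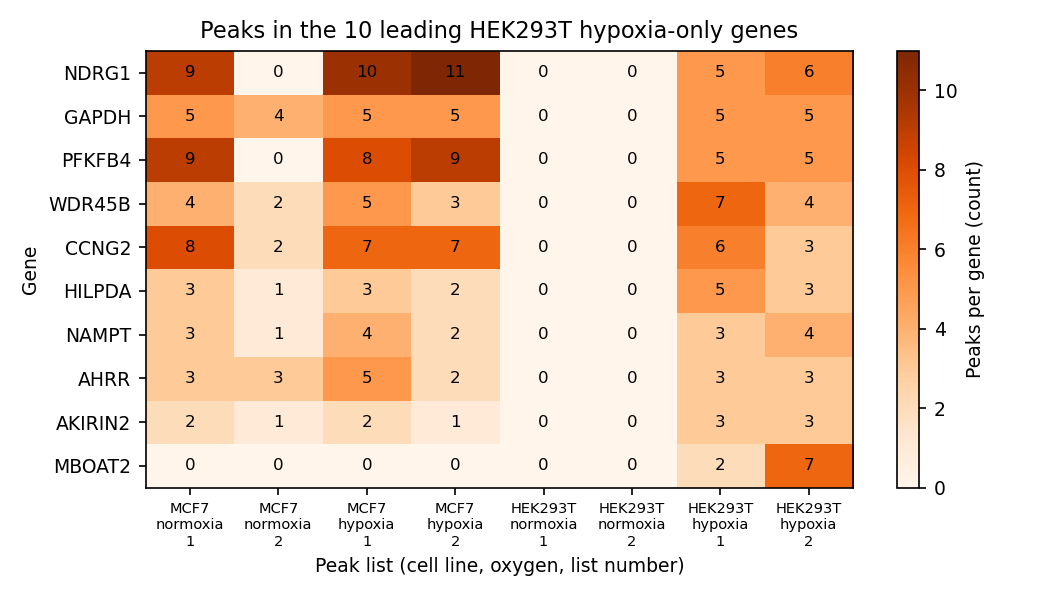
Number of peaks (colour and printed count) in the 10 leading HEK293T hypoxia-only genes (vertical axis) in each of the 8 peak lists (horizontal axis). All 10 genes hold 0 peaks in both HEK293T normoxia lists. NDRG1 and PFKFB4 hold 9 peaks each in the list labelled MCF7 normoxia 1 and 0 in MCF7 normoxia list 2.

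In MCF7, the same question gave a different picture, and the 2 normoxia lists differed from each other. The hypoxia-response list held 51.5 of every 10000 peaks (42.5 to 61.9) in the list labelled MCF7 normoxia 1 and 25.4 (16.9 to 36.7) in normoxia list 2, against 50.6 (42.8 to 59.3) and 69.9 (58.5 to 82.8) in the hypoxia lists. NDRG1 held 9 and 0 peaks in the normoxia lists and 10 and 11 in hypoxia, PFKFB4 held 9 and 0 and then 8 and 9, and PFKFB3 held 9 and 1 and then 12 and 11. KDM4B, a histone demethylase gene, held 4 and 2 and then 12 and 15. Of 27 members bound in MCF7, 8 had more peaks in both hypoxia lists than in either normoxia list. Without the list labelled MCF7 normoxia 1 that number was 25, but the remaining normoxia list is the shortest, and 28 of 44 nuclear speckle and spliceosome genes and 17 of 18 glycolysis genes were then also higher in both hypoxia lists. The difference in level was 21.7 per 10000, with exact permutation p = 0.667, 34.8 without the list labelled MCF7 normoxia 1, 8.68 without normoxia list 2 and 12.1 without hypoxia list 2. With peaks of at least 5 bases it was 12.6.

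Glycolysis genes in MCF7 held 65.2 (55.0 to 76.8) and 60.8 (47.2 to 77.2) of every 10000 peaks in normoxia and 56.3 (48.1 to 65.5) and 80.5 (68.2 to 94.2) in hypoxia, overlapping ranges. PFKP, the platelet isoform of phosphofructokinase, held 20 and 6 peaks in normoxia and 22 and 24 in hypoxia. HK2 held 7 and 1 and then 14 and 10, and HK1 held 16 and 7 and then 19 and 15.

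Genes bound only in the MCF7 hypoxia lists numbered 520, and the number was 2231 without the list labelled MCF7 normoxia 1. The leading genes were the pseudogene RRN3P3 (4 and 4 peaks), PRPSAP1 (5 and 3), the diacylglycerol kinase gene DGKD (3 and 4), the prostaglandin E synthase gene PTGES2 (4 and 3), RUSC1-AS1 (4 and 3) and the phosphatase gene PTPN22 (3 and 3). KIAA0513 (2 and 6), FLII (5 and 2), IVNS1ABP (5 and 2) and ACSF3 (4 and 2) followed. With lists drawn to equal length, hypoxia-only genes numbered 363 and normoxia-only genes 335 in MCF7, so most of the difference in number was not kept at equal length. Dropping peaks at random makes some bound genes look unbound, so these draws do not show how many genes are specific to an oxygen level. At full length 35 genes were bound in both MCF7 normoxia lists and neither hypoxia list, led by WDFY2 (3 and 1), ADGRA3 (2 and 1), TPM3P9 (1 and 2) and ZNF730 (2 and 1). The other 6 named, ARL14EP, ATP6V1H, C10orf88B, CHORDC1P4, DDX31 and DUS2, held 1 peak in each normoxia list. The hypoxia-response list was not enriched among MCF7 hypoxia-only genes (odds ratio 0.663, adjusted p = 1 by Fisher's exact test). This test could not show enrichment, because the list labelled MCF7 normoxia 1 bound 26 of the 27 members bound in any MCF7 list. At most 1 member could therefore be hypoxia-only, and that member, MXI1, was.

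The size of these sets did not follow oxygen alone. In MCF7 the pair of normoxia list 1 and hypoxia list 1 had 1000 genes bound in both and in neither other list, against 520 for the hypoxia pair and 35 for the normoxia pair. In HEK293T, normoxia list 2 shared 592 such genes with hypoxia list 2 and 437 with hypoxia list 1, against 319 and 287 for the hypoxia and normoxia pairs, while normoxia list 1, the shortest, shared 45 with hypoxia list 1 and 42 with hypoxia list 2. Lists of the same lengths, drawn at random a single time from the pooled peaks of each line, gave 545 hypoxia-only genes in MCF7 and 336 in HEK293T. The observed hypoxia-only counts were no larger than these, but a single draw gives no spread to judge them by. Normoxia-only counts were not simulated.

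**Figure D3:**
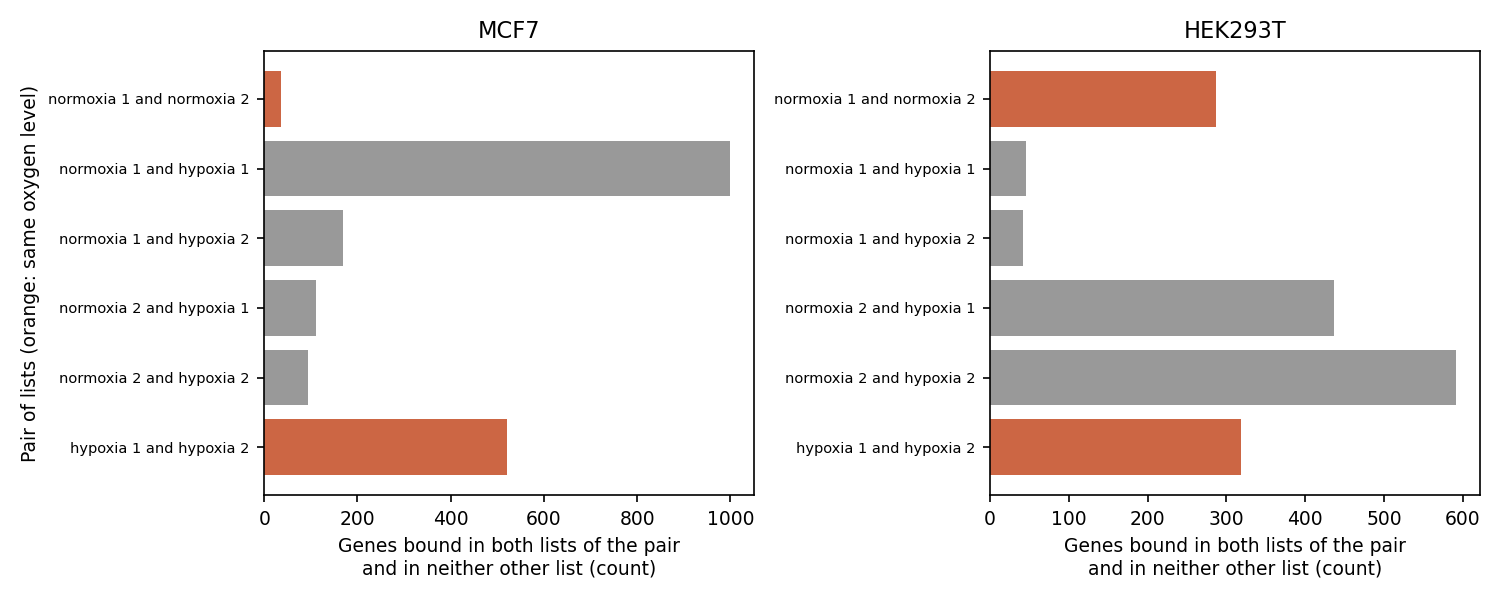
Number of genes bound in both lists of a pair and in neither other list of the cell line (horizontal axis) for the 6 pairs of lists (vertical axis) in MCF7 and HEK293T, with pairs of the same oxygen level in orange. In both lines a pair of different oxygen level gives the longest bar, 1000 genes in MCF7 and 592 in HEK293T.

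At the level of sites, 1596 of 64405 merged MCF7 regions were found only in both hypoxia lists and 677 only in both normoxia lists. In HEK293T the counts were 1042 and 723 of 36564. With lists drawn to equal length the order turned in both lines, with 455 hypoxia-only and 749 normoxia-only regions in MCF7 and 443 and 490 in HEK293T. Such draws make regions look absent where peaks were dropped, so the turned order is no evidence of more normoxia-only sites. The pairs of different oxygen level gave 783 to 2687 regions in MCF7 and 304 to 1160 in HEK293T, so neither line's hypoxia-only count exceeded the range for such pairs. The leading HEK293T hypoxia-only regions, by covered bases in the list with fewer, included an exon-intron site in LINC01138 and RNVU1-2 (chromosome 1, 148388593 to 148388628), an intronic site in TTC3 (chromosome 21, 37111369 to 37111411), a coding site in PABPC3 (chromosome 13, 25096922 to 25096963) and an intronic site in MND1 (chromosome 4, 153392857 to 153392886). The leading HEK293T normoxia-only regions included exon-intron sites in CLVS1 with NPM1P6 (chromosome 8, 61202483 to 61202524) and in SOX2-OT with RNU6-4P (chromosome 3, 181231809 to 181231845), and an intronic site in NCOA1 (chromosome 2, 24522670 to 24522701). In MCF7, the leading hypoxia-only region was intronic in RBMS2 (chromosome 12, 56567414 to 56567493, 80 bases), and the leading normoxia-only region was a coding exon of UST (chromosome 6, 148747474 to 148747517).

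SRSF1 peaks lay mainly in exons, and more so in MCF7. Exons with coding sequence held 59.3%, 56.9%, 62.5% and 55.1% of peaks in the MCF7 lists (normoxia 1 and 2, then hypoxia 1 and 2) and 45.6%, 45.8%, 51.3% and 48.4% in the HEK293T lists in the same order. Introns held 5.83%, 6.81%, 5.49% and 9.82% in MCF7 and 19.1%, 25.7%, 19.2% and 28.2% in HEK293T. Between oxygen levels the mean intron share differed by 1.34 percentage points in MCF7 and 1.28 in HEK293T, less than the spread between lists in each line, with exact permutation p = 0.611 over both lines (n = 4 lists each).

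Exons without coding sequence held a smaller share in HEK293T hypoxia, 12.4% ± 1.73 against 18.9% ± 2.68 in normoxia (SD, n = 2 lists). Exon peaks annotated to 3' untranslated regions alone, a class given for HEK293T, held 12.3% (95% confidence interval 11.5 to 13.1) and 9.28% (8.83 to 9.73) in normoxia and 3.65% (3.31 to 4.01) and 4.16% (3.82 to 4.53) in hypoxia. Both hypoxia lists lay below both normoxia lists, at the smallest p that exact permutation allows (p = 0.33). Among HEK293T regions, exons without coding sequence made up 26.1% (23.0 to 29.5) of the 723 normoxia-only and 10.7% (8.84 to 12.7) of the 1042 hypoxia-only regions. In MCF7, exons without coding sequence held 23.3% ± 0.254 in normoxia and 22.1% ± 1.69 in hypoxia (SD, n = 2), and over both lines exact permutation gave p = 0.111, adjusted to 0.417 by Benjamini-Hochberg over the 5 gene parts.

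**Figure D4:**
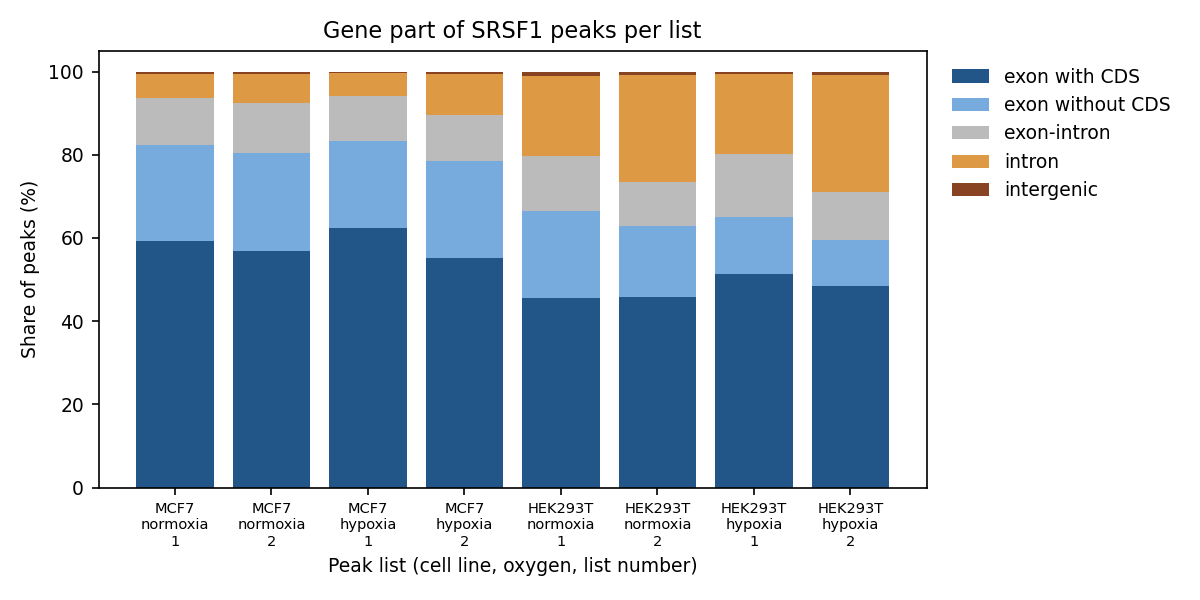
Share of peaks (vertical axis, percent) by annotated gene part in each of the 8 peak lists (horizontal axis), 1 stacked bar per list without error bars. Introns hold 19.1% to 28.2% of peaks in the HEK293T lists and 5.49% to 9.82% in the MCF7 lists.

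Lists of one oxygen level were not clearly more alike than lists of different levels. In HEK293T, 28.2% of the shorter list's peaks on average overlapped a peak of the other list for the 2 same-oxygen pairs, against 24.3% for the 4 different-oxygen pairs. In MCF7 the averages were 23.0% and 23.8%. Between the lines the average was 7.02% over 16 pairs. The base-level Jaccard index averaged 0.0933 and 0.0861 in HEK293T for same and different oxygen, 0.0650 and 0.0692 in MCF7, and 0.0164 between lines. The highest gene-level Jaccard index in MCF7, 0.759, joined the list labelled normoxia 1 to hypoxia list 1.

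The second comparison was between the cell lines. ESR1, the oestrogen receptor gene, held 17, 9, 23 and 7 peaks in the MCF7 lists and 0 in each HEK293T list, and the oestrogen-responsive gene GREB1 held 27, 14, 32 and 14 in MCF7. VIM, encoding vimentin, held 2, 4, 4 and 4 peaks in HEK293T and 0 in each MCF7 list, and LIN28B, a regulator of let-7 microRNAs, held 2, 4, 1 and 2. Of the 20 HEK293 markers, 9 were bound in any HEK293T list, and PAX8 and PRSS23 from the same list each held 0, 1, 2 and 2 peaks in MCF7 and 0 in HEK293T. Of 13456 genes, 1355 were bound in all 4 MCF7 lists and no HEK293T list, and 272 in all 4 HEK293T lists and no MCF7 list. The MCF7 set held 9 of the 17 luminal breast markers bound in any MCF7 list, against 1.97 expected (adjusted p = 0.000485 by Fisher's exact test), and the HEK293T set held 6 of the 9 HEK293 markers bound in any HEK293T list, against 0.277 expected (adjusted p = 1.62e-06). Adjustment was by Benjamini-Hochberg over 26 tests, against genes in any list of the line. A narrower background, genes in at least 4 of the 8 lists, admits a gene absent from the other line only if it is in the set. Against that narrower background, nuclear speckle and spliceosome genes had 0 of 43 members in the MCF7 set (7.39 expected, adjusted p = 0.0036 by Fisher's exact test), DNA replication and repair genes 0 of 30 and translation factors 1 of 43 (both adjusted p = 0.0355 by Fisher's exact test). None of these low numbers passed against genes in any list of the line (adjusted p = 0.0697, 0.284 and 0.284 by Fisher's exact test) or of both lines. The MCF7 set was 333 genes when all lists were drawn to equal length.

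Leading MCF7 genes with no HEK293T peak were PREX1, a Rac exchange factor gene (23, 24, 31 and 24 peaks), the steroid receptor coactivator gene NCOA3 (21, 17, 36 and 24), AGRN (20, 15, 18 and 21), DSCAM (52, 14, 56 and 39) and LLGL2 (13, 13, 14 and 14). BAGE2, IGSF3, MLPH, SREBF1 and SOGA1 completed the set. In HEK293T they were the axon guidance genes SLIT2 (23, 74, 20 and 28) and its receptor ROBO1 (17, 32, 20 and 20), ADAMTS1 (11, 16, 16 and 15), MID1 (15, 27, 10 and 17) and AKAP12 (6, 9, 7 and 12), followed by SCMH1, USP16, TUT4, LDHB and SH3PXD2A. Genes bound in all 8 lists numbered 2015, against 1191 expected if the genes bound in all 4 lists of each line were independent sets.

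Genes with most peaks differed between the lines. In MCF7 they were BRWD1 (77, 33, 79 and 69 peaks), EIF2B5 (68, 41, 84 and 56), HUWE1, DYNC1H1, DSCAM, LAMA5, MYH9, EIF4G1, PRKDC and ZNF512B. In HEK293T they were TTC3 (16, 71, 41 and 49), SLIT2, DYRK1A (13, 37, 40 and 32), BRWD1, TPR, PAXBP1, SON, ROBO1, DDX17 and ATRX. TTC3, DYRK1A, BRWD1, PAXBP1, SON and DSCAM lie on chromosome 21, where most rows repeated a position before repeats were removed. SON, a nuclear speckle scaffold, held 18, 33, 20 and 25 peaks in HEK293T and 11, 9, 14 and 11 in MCF7.

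Hypoxia-only genes of the lines overlapped in 15 genes, against 8.60 expected from independent sets among 7082 genes bound in both lines. The odds ratio was 1.84 with p = 0.0252 by one-sided Fisher's exact test. The 2015 genes bound in all 8 lists are in this background but can enter neither set. The expected number is therefore a low baseline, and the p-value may overstate the overlap. No gene was normoxia-only in both, where 0.535 were expected, so this is no contrast with the hypoxia-only overlap. The overlap included LRP1, AMPD3, NPC1 and FEM1C, and no member of the hypoxia-response list, of which the MCF7 hypoxia-only genes held only MXI1. It did not pass when lists were drawn to equal length (median p = 0.153 by Fisher's exact test), nor with peaks of at least 5 bases (p = 0.245) nor without HEK293T normoxia list 1 (p = 0.0697).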

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

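All tests in this part were chosen after the result they bear on was seen. Rows that repeat a position made up 17.2% of the deposited rows and 78.9% of those on chromosome 21, a signal in rows that the comparisons do not use. On chromosome 16 they made up 33.7% to 48.1% of rows per list. Chromosome 5 differed between the lines, with 12.6% to 20.4% and up to 21 copies in MCF7, and 3.16% to 4.50% and at most 3 copies in HEK293T. Copies at shared positions were compared on chromosome 21 only. Of repeated chromosome 21 positions, 88.8% named 1 gene, which argues against a listing of 1 row per overlapping gene. In 100% of the 45 pairs of repeated positions found in an MCF7 and a HEK293T list (only 8 distinct positions), the number of copies was equal, so a processing step tied to genome position is a candidate explanation, and no biological explanation was tested. Peaks per bound gene were also higher on chromosome 21 after repeats were removed, from 3.64 against 2.14 elsewhere in MCF7 normoxia list 2 to 7.73 against 2.61 in HEK293T normoxia list 2, and repeats do not account for that.

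Hypoxia-response peaks in the list labelled MCF7 normoxia 1 lay at the level of the MCF7 hypoxia lists, at 51.5 per 10000 with 26 members bound, against 15 members in normoxia list 2 and 27 and 27 in the hypoxia lists. Random loss of peaks does not account for it, since random draws to the length of normoxia list 2 kept 22.4 members bound on average (18 to 25 over 100 draws). The draws do not model a loss that differs between genes, and depth is unknown. Normoxia list 2 also differed elsewhere, with translation factors at 177 per 10000 against 97.7 to 117 in the other MCF7 lists. A swap between MCF7 normoxia and hypoxia lists would need a hypoxia list at the low level, where the lower stood at 50.6 per 10000. Genes bound only in the HEK293T hypoxia lists held 219 of every 10000 peaks in the list labelled MCF7 normoxia 1, against 175 in normoxia list 2 and 238 and 231 in the hypoxia lists, and genes bound only in the HEK293T normoxia lists held 198 and 180 in the normoxia lists. Without members of the fixed gene lists, the HEK293T hypoxia-only genes held 199 and 165 in the MCF7 normoxia lists and 221 and 208 in the hypoxia lists. These are values of single lists, with no spread between lists to set them against, and members differed, as KDM4B at 4 peaks lay nearer normoxia list 2 (2) than the hypoxia lists (12 and 15). RNA of hypoxic cells in this list, through a single wrong label or mixed RNA, may account for the pattern, but it cannot be told apart from the ASO arm, since no list is tied to an ASO (the HEK293T normoxia lists differed by 1.97 per 10000).

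CERCAM had more peaks in both hypoxia lists than in either normoxia list in MCF7, and fewer in both in HEK293T. Its mean peak number was 3 higher in hypoxia in MCF7 (4 and 2 peaks in normoxia, 7 and 5 in hypoxia) and differed by -2.5 in HEK293T (2 and 3, then 0 and 0). Among 162 measures and genes looked at, it alone had lists that separated fully in opposite directions, while mean differences of opposite sign with overlapping lists were not counted. CERCAM was looked at because it is a leading HEK293T normoxia-only gene, so its separation in HEK293T was fixed by that choice. The number of such cases that chance would give was not worked out, and the difference between the lines was not tested.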

How the results depend on the processing

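The minimum of 2 peaks per gene, protein-coding genes, 50% overlap, strand, shares of bases, the background and leaving out lists (other than jointly with the background) were chosen before the data were examined, and the other settings after. No paired analysis was possible because list numbers are not tied to the replicate numbers of the labels. Settings that need a peak value (best-scoring peaks, a stricter score), a genome (motifs) or read counts were not run. Outside leave-one-out, 153 values kept their direction and side of the threshold, or moved by less than the spread between lists (1.5 times for counts), while 28 moved further, 9 no longer passed and 2 reversed. For those the cause was not tested. Among named genes, 923 values stayed within the spread and 92 did not. Unknown depth limits all counts.

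Drawn to equal length, MCF7 normoxia-only genes numbered 335, hypoxia-only regions 455 in MCF7 and 443 in HEK293T, and MCF7-only genes 333. The MCF7 hypoxia-response odds ratio became 1.497 (reversed, adjusted p = 1 by Fisher's exact test), the MALAT1 difference in MCF7 -0.925 peaks, and the odds ratio of shared hypoxia-only genes 1.54. With at least 2 peaks per gene, normoxia-only and hypoxia-only genes numbered 0 and 52 in MCF7 and 20 and 41 in HEK293T, and MCF7-only and HEK293T-only genes 427 and 49. At 50% overlap, MCF7 hypoxia-only regions numbered 1024, and merging within 50 bases left 381 MCF7 normoxia-only regions. With rows as deposited, the HEK293T difference was 39.3 per 10000 for hypoxia response and 41.3 for glycolysis. With peaks naming 1 gene or none, the MCF7 exon-intron difference was -0.0478 percentage points, HEK293T normoxia-only genes 178 and MCF7-only genes 885.

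For gene lists between the cell lines, members of the MCF7-only genes minus the number expected no longer passed with genes in any list of the line or in any of the 8 lists as background, at -5.21 and -4.53 for nuclear speckle and spliceosome, -4.10 and -3.43 for translation factors and -3.59 and -3.12 for DNA replication and repair. The expected numbers of these lists were lower with the larger backgrounds, and both marker lists still passed.

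With peaks of at least 5 bases, MCF7 normoxia-only genes numbered 155, MCF7 hypoxia-only regions 941, HEK293T normoxia-only and hypoxia-only regions 388 and 605, and MCF7-only and HEK293T-only genes 777 and 178. Odds ratios for hypoxia response were 1.19 in MCF7 (reversed, not passing in either setting) and 3.07 in HEK293T (no longer passing), and for shared hypoxia-only genes 1.22. Per 10000 peaks, glycolysis differed by -9.29 in MCF7 and 4.22 in HEK293T, and hypoxia response by 29.2 in HEK293T. The MALAT1 difference in HEK293T was -0.5 peaks.

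Leaving out each list left 1 list for its condition, so counts could only grow by construction. Normoxia-only genes ranged from 86 (without MCF7 hypoxia list 2) to 444 (without normoxia list 2) in MCF7, and from 492 (without normoxia list 2 or hypoxia list 1) to 1536 (without normoxia list 1) in HEK293T. Hypoxia-only genes ranged from 738 to 2231 in MCF7, highest without the list labelled MCF7 normoxia 1, and from 414 to 1282 in HEK293T, highest without normoxia list 2. Normoxia-only regions ranged from 1122 to 14867 in MCF7 and 978 to 12022 in HEK293T, and hypoxia-only regions from 2095 to 22929 and 1276 to 9086. HEK293T-only genes ranged from 275 to 410, highest without HEK293T normoxia list 1, and MCF7-only genes from 1383 to 2008. The hypoxia-response odds ratio ranged from 0.222 to 2.18 in MCF7, reversed without the list labelled MCF7 normoxia 1, and from 3.91 to 6.41 in HEK293T. It no longer passed when a HEK293T hypoxia list was left out together with a background of genes in any list, a pair of changes chosen after seeing the data (4.02 without list 1, 3.91 without list 2), while that background alone gave 9.54 and passed. Shared hypoxia-only genes had odds ratios of 1.45 to 1.92, no longer passing without HEK293T normoxia list 1 (1.56).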

Other observations

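The tests of intron shares below were chosen after the result was seen. Outside the hypoxia lists, HEK293T chaperone transcripts held more peaks in hypoxia for 8 of 22 bound members of the heat shock and chaperone list, and fewer for 1. The 16.7% that chance gives in each direction holds only without ties and with equal list lengths, so it is no exact baseline. HSP90AA1, the inducible cytosolic HSP90 gene, held 7 and 7 peaks in normoxia and 17 and 11 in hypoxia. HSPA5, the endoplasmic reticulum chaperone BiP, held 4 and 3 and then 8 and 7, and PDIA4, a protein disulfide isomerase gene, held 1 and 2 and then 7 and 6. The share of peaks in the whole list overlapped between the oxygen levels, 111.6 and 67.9 per 10000 in HEK293T normoxia and 118.8 and 87.2 in hypoxia (exact permutation p = 0.667). In MCF7, 1 of 23 members had more peaks in both hypoxia lists, and HSP90AA1 held 10 in every list. The share of the whole list was lower in both MCF7 hypoxia lists, 65.4 and 67.2 per 10000 against 79.8 and 113.5 in normoxia. Exact permutation gave p = 0.33, the smallest possible, and confidence intervals of normoxia list 1 and the hypoxia lists overlapped. The list was not enriched among hypoxia-only genes of either line, and could not be. HEK293T normoxia list 2 bound all 22 members bound in that line, and the list labelled MCF7 normoxia 1 all 23.

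Of the SR protein list, 3 of 12 bound members had more peaks in both HEK293T hypoxia lists and 1 had fewer, and 3 of 11 and 0 in MCF7. For hnRNPs these were 3 and 3 of 26 in HEK293T and 2 and 0 of 26 in MCF7, for nuclear speckle and spliceosome genes 5 and 4 of 44 and 5 and 1 of 45, and for long noncoding RNAs 4 and 2 of 23 and 2 and 0 of 25. SRSF5, an SR protein gene, held 11 and 9 peaks in HEK293T normoxia, 12 and 12 in hypoxia, and 7 to 8 in the MCF7 lists, and SRSF11 held 10 and 13 and then 10 and 9 in HEK293T. TRA2A held 4 and 7 and then 3 and 1, and SRSF4 held 3 and 9 and then 3 and 5. Among hnRNP genes, HNRNPH1 held 9 and 11 peaks in HEK293T normoxia and 14 and 13 in hypoxia, while HNRNPC held 8 and 13 and then 7 and 6. DYRK1A, a kinase gene of the nuclear speckle list, held 13 and 37 and then 40 and 32. PVT1, a long noncoding RNA beside MYC, held 16 and 14 peaks in MCF7 normoxia and 28 and 25 in hypoxia, against 3 to 4 in HEK293T. Of the translation factor list, 0 of 44 bound members separated the oxygen levels in MCF7, and in HEK293T 4 had more and 4 fewer in both hypoxia lists. The oxidative phosphorylation list had 0 of 34 members with such a difference in MCF7 and 1 of 23 in HEK293T. The DNA replication and repair list had 2 of 31 higher in MCF7, and 2 higher and 3 lower of 30 in HEK293T. Replication-dependent histone genes had 1 of 19 higher in MCF7 and 2 of 11 in HEK293T. Peak numbers depend on list length. Per 10000 MCF7 peaks, translation factors held 117 and 177 in normoxia and 97.7 and 107 in hypoxia. Nuclear speckle and spliceosome genes held 120 and 135, then 116 and 109, and hnRNPs 73.0 and 92.6, then 63.7 and 64.6. Each share was lower in both hypoxia lists (exact permutation p = 0.33, the smallest possible). Confidence intervals of normoxia list 1 and the hypoxia lists overlapped. In HEK293T these shares overlapped between oxygen levels.

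Intron share was higher in list 2 than in list 1 of each of the 4 conditions, 9.82% against 5.49% in MCF7 hypoxia and 28.2% against 19.2% in HEK293T hypoxia. An effect of list length in the same direction in both lines does not account for it, as the higher list was the longer one in 2 of 4 pairs. List 2 was the shorter in both MCF7 pairs and the longer in both HEK293T pairs. An effect of length that differs between the lines therefore cannot be excluded. Chromosome 21 peaks do not account for it, since all 4 pairs kept the order without chromosome 21. The ASO arm, replicate or library batch carried by the list number may explain it, but these cannot be told apart because the labels tie the numbers to none of them, and 4 pairs going the same way has a chance of 0.125.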
